A study of Homo sapiens with 12 samples.

How the data were processed

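Messenger RNA was measured in SH-SY5Y cells, an established human neuroblastoma line with features of immature sympathetic neurons. Per the labels, wild-type cells were set against cells in which FMR1 had been knocked out. FMR1 encodes FMRP, an RNA-binding protein that regulates translation and whose loss underlies fragile X syndrome. The labels name 3 knockout lines, made independently. Cells of each genotype were kept for 2 weeks in heavy or in light SILAC medium. SILAC media carry amino acids with heavy or ordinary stable isotopes, so that proteins of 2 cultures can be told apart by mass spectrometry; only RNA was used here. The 4 groups hold 3 libraries each, 12 in all. In the knockout groups the replicate number is the number of the line, so each line gave 2 libraries, 1 per medium. In the wild-type groups the labels give only a number, and nothing says that these libraries came from separately derived cells, so the spread between them may be technical in part. Loss of FMR1 and the making of a line therefore cannot be told apart in knockout against wild type, also for changes shared by all 3 lines.

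The deposited table holds raw whole-number counts of reads per gene for 59087 features in the 12 libraries. Per the labels' protocols, the libraries were poly(A)-selected and stranded. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.19.0, reads were aligned with STAR 2.7.0f to GRCh38.p13, reads per gene were counted with featureCounts of Subread 1.6.4, and DESeq2 1.22.1 was run in R 3.5.1. The annotation release, the strand setting of the counting and the treatment of reads that match several genes are not given in the sources used here. Values of overlapping, antisense and near-identical genes are therefore uncertain. The values of a library summed to between 25935152 and 40257027 counts. None of the features was a total or an unassigned class, and 27691 features were at 0 in every library. Gene positions came from GENCODE release 29 on GRCh38, in which 56206 features were found by symbol.

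The counts were tested as deposited, with edgeR 4.0.16 in R 4.3.3: TMM normalisation, removal of low counts by filterByExpr, robust quasi-likelihood fits and F tests, and Benjamini-Hochberg adjustment at 0.05. An adjusted p below means this test unless another tool is named. Levels are CPM, counts divided by the TMM-scaled library size, computed here and given as mean ± SD; log2 fold changes have standard errors (SE) derived from the F statistic. Knockout and wild type were compared over both media (all 12 libraries, medium as a covariate), then in heavy and in light medium alone (6 libraries each). Heavy and light medium were compared over both genotypes and within each. The interaction of genotype and medium was tested on all libraries, and the difference among the 3 knockout lines on the 6 knockout libraries, with medium as a covariate. Since each line enters the fit over both media with 2 libraries, that fit treats 6 knockout libraries as independent although they stand for 3 lines. A fit on counts summed per line, 3 against 3, was therefore set beside it.

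Before the data were examined, 36 gene lists with 1117 entries were fixed from general knowledge of neuroblastoma cells, FMRP and cell culture; 1113 entries were in the table. Each list was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

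The genes to be named were fixed by rule beforehand: FMR1 and its paralogs FXR1 and FXR2 always; then the 12 largest rises and the 12 largest falls among genes with a symbol and a mean of at least 1 log2 CPM, past 0.05 over both media, in each medium and on summed lines, with every knockout library on 1 side of the wild-type range of its medium. For falls, where 0 genes met the condition on single media, that condition was dropped, as the rule provided. For each list past the threshold, and for lists of FMRP targets, nonsense-mediated decay and cell identity whatever their result, up to 4 members with the smallest p were named. For the media and the interaction the rule took the 3 genes with the smallest p where none passed, and for the lines the 8 genes with the largest range among line means. Genes named outside the rule are said to be so, and some members that the rule picked are not reported here.

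Alternatives fixed beforehand were RLE factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, each library left out in turn, each knockout line left out, the replicate number as a block, the line as a correlated block, counts summed per line, glmTreat against a fold of 1.5, and 1 estimate of the spread shared by all 12 libraries. Deviations from the group means were correlated to see whether numbers pair libraries. Knockout libraries of 1 number come from 1 line, per the labels, and are paired by that; their correlations were 0.107 in line 1, 0.783 in line 2 and 0.779 in line 3. Wild-type libraries of 1 number had correlations of 0.17, 0.074 and -0.153 and share only a number. Knockout and wild-type libraries share only a number too, with correlations of -0.243, -0.06 and -0.185 in heavy and -0.058, -0.163 and -0.034 in light medium. In knockout against wild type the block by number therefore pairs libraries without a basis in the design. Chi-square per degree of freedom between replicates lay between 4.62 and 49.33, so no pair agreed within sampling noise.

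The test was tried on simulated counts with known changes for 4 of the comparisons; the others use the same functions and were not simulated. In a simulation of the fit over both media on 16484 genes, 62% of genes changed 1.5-fold, 84% of those changed 2-fold, 98% of those changed 4-fold and 96% of those changed 8-fold were called, and 4% of the calls were false. In one of knockout against wild type in heavy medium the shares called were 30%, 72%, 80% and 98%, with 15.2% of the calls false. In one of the media in wild type they were 78%, 90%, 100% and 98%, with 5.2% false. In one of the media in knockout they were 10%, 58%, 90% and 98%, with 6.6% false. Simulated libraries were drawn independently, whereas the 2 libraries of a knockout line share that line. The 4% is therefore no estimate of the false calls in the real fit over both media.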

Results

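Poly(A) RNA was sequenced from wild-type and FMR1-knockout SH-SY5Y cells grown in heavy or light SILAC medium, with 3 libraries in each of the 4 groups. In the knockout groups the 3 libraries are 3 independently made lines, numbered 1 to 3, each present once per medium. Wild-type libraries held 29181584, 31330775 and 35589916 counts in heavy medium and 30864161, 40257027 and 30257291 in light medium. Knockout lines 1, 2 and 3 held 34854477, 34621562 and 30479130 counts in heavy medium and 35162761, 25935152 and 37840662 in light medium. TMM factors lay between 0.982 and 1.028.

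FMR1 mRNA (ENSG00000102081.14; chromosome X, 147911951 to 147951125, plus strand, GRCh38), the targeted transcript, was lower in all 6 knockout libraries than in any wild-type library. It stood at 37.8 ± 2.14 CPM (SD, n = 6) in wild type and at 12.4 ± 5.34 CPM (SD, n = 6) in knockout, a log2 fold change of -1.62 (SE 0.217, edgeR adjusted p = 0.00131). Line 2 had 12.8 CPM in heavy and 11.5 CPM in light medium, line 3 had 7.12 and 9.08 CPM, and line 1 had 11.4 CPM in light medium. The library labelled knockout line 1, heavy, had 22.5 CPM, 59.6% of the wild-type mean. Without that library the change was -1.86 (adjusted p = 8.55e-06); in light medium alone it passed (adjusted p = 0.000404), and in heavy medium alone it did not (adjusted p = 0.18). The edit's position is not given in the sources used here, so reads of an edited transcript would be counted with the rest. The paralog FXR1 had a log2 fold change of -0.08 (SE 0.04, adjusted p = 0.16) and FXR2 of -0.06 (SE 0.046, adjusted p = 0.348); neither passed.

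**Figure D1:**
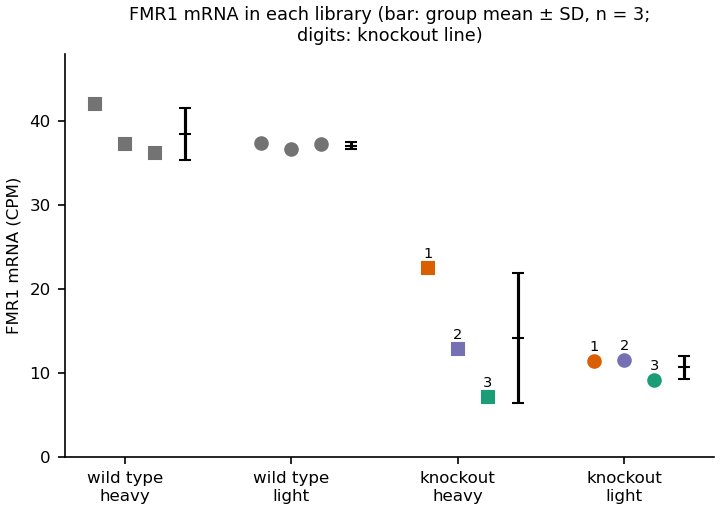
FMR1 level in CPM in each of the 12 libraries, by genotype and medium, with bars for group means ± SD (n = 3); digits mark the knockout lines. Wild-type libraries lie between 36.2 and 42 CPM, and the knockout libraries between 7.12 and 22.5 CPM, the highest being line 1 in heavy medium.

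The first comparison set knockout against wild type over both media. Among the genes that met the naming rule, which asks for calls in each medium and on summed lines, the largest rises were those of 3 neighbouring genes of the long arm of chromosome X. Genes outside the rule had larger changes, such as SHISA5 (log2 4.41, adjusted p = 0.00462, but 0.0854 on summed lines) and TNFRSF1A (0.0199 CPM in wild type and 10.2 CPM in knockout, adjusted p = 0.00085, and 0.0496 on summed lines, but 0.0875 in heavy and 0.0658 in light medium), both named after their values were seen. GPRASP1 (102651366 to 102659083), which encodes a sorting protein for G protein-coupled receptors, went from 1.2 ± 0.132 to 19.8 ± 7.34 CPM (SD, n = 6 each), 16.5-fold (log2 4.05, SE 0.259, edgeR adjusted p = 1.7e-05). Its relative GPRASP2 (102712176 to 102717733) went from 2.89 ± 0.253 to 41.3 ± 9.83 CPM, 14.3-fold (log2 3.84, SE 0.162, adjusted p = 1.75e-07). The overlapping readthrough transcript ARMCX5-GPRASP2 (102599512 to 102714671) rose 9.49-fold, from 0.627 to 6 CPM (adjusted p = 1.03e-06); it shares exon sequence with GPRASP2, so its own level is uncertain. All 3 genes lie on the plus strand. GPRASP2 was at 24.6 to 53.1 CPM in the 6 knockout libraries.

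The other rises that met the naming rule were smaller. P2RX5, an ATP-gated ion channel, rose 6.26-fold, and ME3, a mitochondrial malic enzyme, rose 5.08-fold. CCDC3 rose 4.22-fold and the phosphohistidine phosphatase LHPP 2.87-fold. The interferon-induced antiviral enzyme OAS3 rose from 11 ± 0.896 to 27 ± 4.09 CPM (SD, n = 6 each; log2 1.30, SE 0.099, edgeR adjusted p = 1.44e-05). The fatty acid-binding protein FABP5 rose 2.24-fold, the actin regulator ARPIN 2.2-fold, MPV17L 2.03-fold and the G protein gamma subunit GNG7 2-fold. For these 9 genes the adjusted p over both media was at most 0.000341 and that on counts summed per line at most 0.0317.

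Of the falls that met the rule, the largest was that of CBLN4. Outside it MSN, named after its value was seen, had -3.83 (adjusted p = 0.0179, but 0.128 on summed lines). CBLN4, a secreted synaptic organiser, fell from 77.5 ± 5.67 to 22.2 ± 12.7 CPM (SD, n = 6 each; log2 -1.87, SE 0.338, edgeR adjusted p = 0.00566). SPOCK1, a matrix proteoglycan, had a log2 fold change of -1.63, the netrin receptor UNC5D of -1.51, the adhesion molecule NCAM2 of -1.49, the proteoglycan versican (VCAN) of -1.34 and the receptor phosphatase PTPRD of -1.19. The protease inhibitor TFPI2 fell from 55.9 ± 2.91 to 22.3 ± 7.5 CPM (log2 -1.34, SE 0.173, adjusted p = 0.000973). MTUS1 had a log2 fold change of -1.54, the aminopeptidase gene XPNPEP2 of -1.46, the transcription factor gene TRPS1 of -1.09 and ABTB2 of -0.92. All 11 passed over both media and on summed lines (adjusted p at most 0.0162 and 0.0353). In heavy medium alone none of the 11 passed, and 0 falling genes met the rule in both media.

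**Figure D2:**
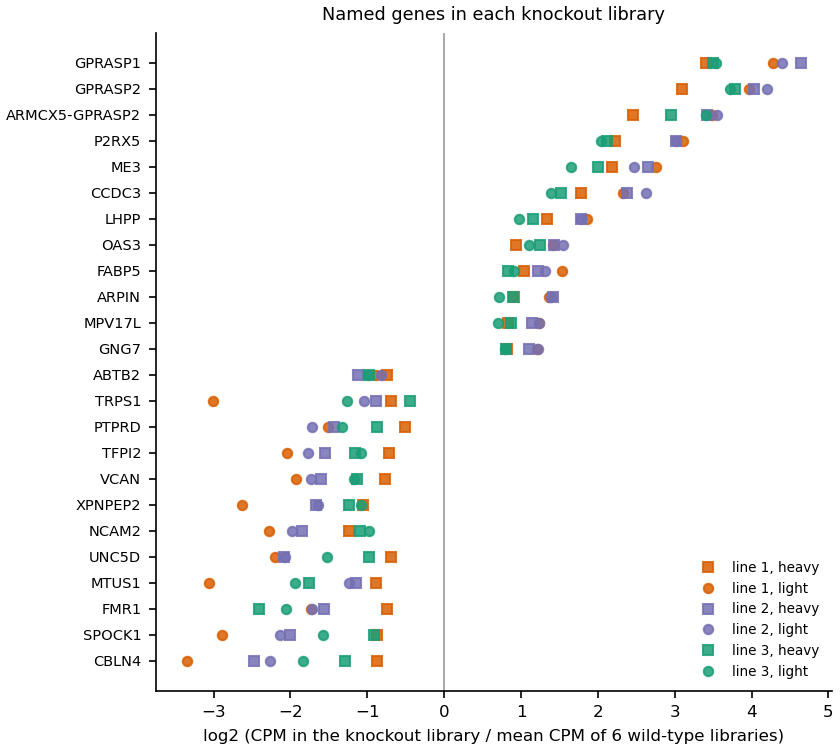
Level in each knockout library relative to the mean of the 6 wild-type libraries, on a log2 scale, for the 12 largest rises and 12 largest falls that met the naming rule; colours mark the lines, squares heavy and circles light medium. GPRASP1, GPRASP2 and ARMCX5-GPRASP2 stand apart with log2 fold changes of 4.05, 3.84 and 3.25; the falls reach -1.87 in CBLN4.

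Of 16704 genes tested, 4135 passed, 2501 of them higher and 1634 lower in knockout; 616 of the higher and 162 of the lower changed at least 2-fold. In 4043 of the 4135 genes (97.8%) the means of all 3 lines lay on the same side of the wild-type mean. The test that picked these genes used the same libraries and favours such agreement, so this share is no separate evidence. Only in 271 (6.6%) did all 3 lines differ by at least 1.5-fold, 187 higher and 84 lower. Line 1 enters with the mean of both its libraries. Its heavy library lay nearer to wild type over many genes, as described below, so this count may be too low. Over all genes tested, 2279 (13.6%) had every knockout library on 1 side of the wild-type range of its medium, where chance gives 0.5% if the 2 libraries of a line are taken as independent, which they are not. With counts summed per line, so that a line counts once, 272 genes passed, 193 higher and 79 lower (71% higher, against 60.5% above), and 268 of them were among the 4135. That fit takes the 3 lines as independent, although the changes of lines 1 and 2 resembled each other (r = 0.903 for line 1 light and line 2, wild type split between them). The summed fit also holds 3 wild-type sums in place of 6 libraries, so its lower count need not come from the lines alone. It left FMR1 past the threshold (edgeR adjusted p = 0.0479).

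Most changes among genes of neurotransmitter release were rises. Of 30 measured genes of the synaptic vesicle and release machinery, 17 rose, 0 fell and 13 did not pass (19 rose when adjusted over the list alone); the median log2 fold change was 0.34. In line 3 it was smaller, 0.085 and 0.132 in heavy and light medium, against 0.543 and 0.420 in line 2. SYT4, a vesicle synaptotagmin, rose by a log2 of 0.56 (SE 0.071, edgeR adjusted p = 0.00049), and SV2A (0.24), SV2C (0.48) and the dynamin gene DNM1 (0.45) rose too. The list passed in camera with an adjusted p = 8.39e-07, and had adjusted p = 0.466 with an estimated correlation. Of 33 genes of neuronal differentiation and cytoskeleton, 16 rose and 4 fell (17 and 4 adjusted over the list alone). Its median was 0.062 and 0.061 in line 3, against 0.377 and 0.430 in line 2 and 0.199 in line 1 light. Among wild-type libraries light 1 was at 0.057 and the others lay between -0.017 and 0.005. Peripherin (PRPH), an intermediate filament of peripheral neurons, rose from 0.206 ± 0.0558 to 8.22 ± 6.89 CPM, with line means of 6.58, 16.5 and 1.54 CPM. NRCAM rose by 0.54, NSG2 by 0.75 and ELAVL4 by 0.72 on the log2 scale. That list had a camera adjusted p of 0.000456, and adjusted p = 0.532 with an estimated correlation.

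Of 28 voltage-gated ion channel genes, 14 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0234; adjusted p = 0.654 with an estimated correlation). Line 3 did not show the shift: the median of this list was -0.011 and 0.013 (log2) in its heavy and light libraries, against 0.54 and 0.437 in line 2 and 0.365 in line 1 light. The sodium channel gene SCN3B (log2 0.61) and the potassium channel gene KCNH6 (1.68) rose, while the T-type calcium channel gene CACNA1G fell (-0.86). Of 18 measured interferon-stimulated genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone): besides OAS3, ISG15 rose by 1.61 from a low level of 0.238 CPM, HERC6 by 0.94 and STAT2 by 0.49 (camera adjusted p = 0.000167; adjusted p = 0.26 with an estimated correlation). Of the 13 protein-coding transcripts of the mitochondrial genome, 10 rose and 0 fell (13 and 0 adjusted over the list alone), by a median log2 of 0.22. In heavy and light medium the median was 0.339 and 0.304 in line 1, 0.078 and 0.249 in line 2 and 0.112 and 0.243 in line 3. The highest wild-type library, heavy 2, was at 0.066. MT-CYB went from 6510 ± 290 to 7580 ± 588 CPM, and the camera adjusted p was 0.000167 (adjusted p = 0.466 with an estimated correlation). Mitochondrial transcripts took 9.53% to 10.53% of the counts in wild-type libraries and 10.87% to 12.16% in knockout libraries.

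The other lists that passed pointed down. Of 24 genes of the unfolded protein response and endoplasmic reticulum chaperones, 14 fell and 0 rose (15 and 0 adjusted over the list alone), among them HSP90B1 (log2 -0.45), calreticulin (CALR, -0.41), DNAJC3 (-0.41) and DNAJB11 (-0.35). The median was -0.24 and the camera adjusted p 8.46e-06 (adjusted p = 0.466 with an estimated correlation). It was -0.074 and -0.138 in the heavy and light libraries of line 3, against -0.387 and -0.446 in line 2 and -0.397 in line 1 light. Of 35 genes of DNA replication and the G1/S transition, 12 fell and 0 rose (16 and 0 adjusted over the list alone). The ribonucleotide reductase subunit gene RRM2 fell by 0.30 on the log2 scale (SE 0.039, edgeR adjusted p = 0.000581), and E2F7 (-0.56), E2F2 (-0.27) and RFC4 (-0.25) fell too. The median of that list was -0.12 (camera adjusted p = 7.79e-05; adjusted p = 0.532 with an estimated correlation), with -0.027 and -0.080 in line 3, -0.159 and -0.107 in line 2 and -0.247 in line 1 light. Of 29 G2/M genes, 5 fell and 0 rose, also adjusted over the list alone, with KIF20A (-0.22), CCNB2 (-0.38), AURKB (-0.41) and MKI67 (-0.21) among them (camera adjusted p = 0.000167; adjusted p = 0.571 with an estimated correlation). The median of the G2/M list was 0.021 and -0.034 in line 3, against -0.188 and -0.196 in line 2 and -0.324 in line 1 light.

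Of 25 cholesterol synthesis and uptake genes, 10 fell and 1 rose, also adjusted over the list alone, including HMGCS1 (log2 -0.43), IDI1 (-0.27), INSIG1 (-0.54) and LSS (-0.29); the camera adjusted p was 0.000355 (adjusted p = 0.571 with an estimated correlation). In line 3 the median of the cholesterol list was -0.084 in heavy medium, within the -0.086 to -0.044 of wild type. In light medium it was -0.010, below the 0.024 to 0.083 of wild type. Line 2 had -0.309 and -0.141, and line 1 light had -0.242. Of 18 Notch pathway genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone): the receptor gene NOTCH3 (-1.05), the target genes HEY1 (-0.66) and NRARP (-0.44), and RBPJ (-0.29) fell (camera adjusted p = 0.0186; adjusted p = 0.571 with an estimated correlation). The Notch median was -0.088 and -0.125 in line 3, against -0.384 and -0.448 in line 2 and -0.282 in line 1 light. The retinoic acid and BMP list passed downward by camera (adjusted p = 0.0331; adjusted p = 0.571 with an estimated correlation), with a median of -0.25, although 3 of its 20 members rose and 2 fell (3 and 3 adjusted over the list alone). ID4 (-1.88) and SMAD7 (-0.48) fell, and MEIS2 (0.61) and CRABP2 (0.49) rose. Its median was 0.132 and -0.097 in line 3, against -0.559 and -0.466 in line 2 and -0.310 in line 1 light. Without the heavy library of line 1 that list no longer passed (adjusted p = 0.062). The list of FMRP and its paralogs passed downward through FMR1 alone, 1 of 3 members, also adjusted over the list alone (camera adjusted p = 0.0234; adjusted p = 0.339 with an estimated correlation). With an estimated correlation 0 of the 36 lists passed, the smallest adjusted p being 0.26, against 12 in camera with the preset correlation and 11 in fry, which did not call voltage-gated channels, G2/M, Notch or retinoic acid genes. Of the list members named, NRCAM, SYT4, CACNA1G, OAS3, ISG15, HERC6, RRM2, ID4, S100A6, ANXA2, ATP2B2 and FMR1 also passed on counts summed per line (adjusted p at most 0.0479).

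**Figure D3:**
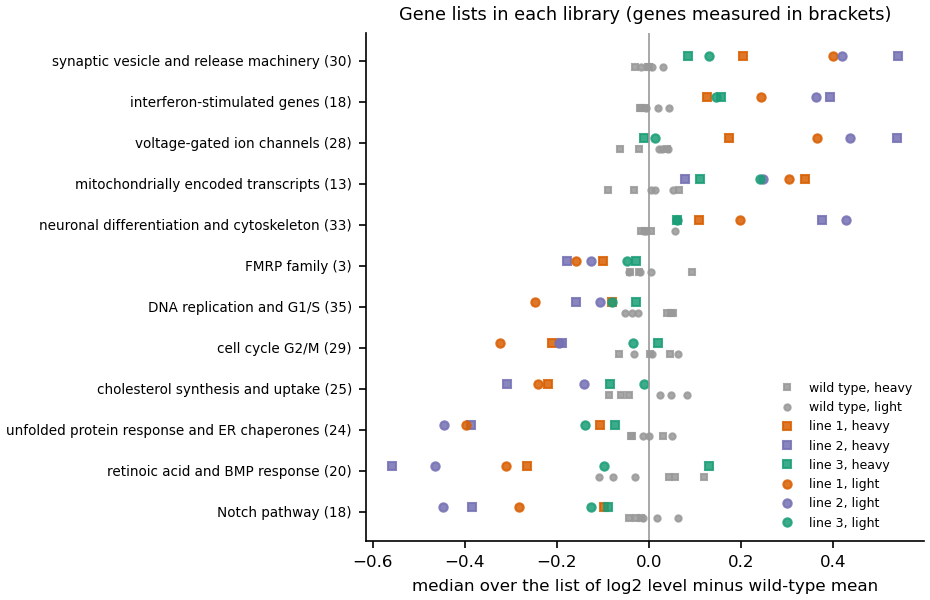
Median over the members of each list that passed of the log2 level minus the wild-type mean, 1 point per library; colours mark the lines, grey wild type, squares heavy and circles light medium, and brackets hold the number of genes measured. Over both media synaptic vesicle genes have a median fold change of 0.34 and unfolded protein response genes of -0.24 on that scale.

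Lists of FMRP targets and of RNA decay did not pass. Of 57 long synaptic and cytoskeletal mRNAs described as FMRP ligands, 13 rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 0.123). The calcium pump gene ATP2B2 (log2 0.76) and NAV1 (0.88) rose. Of 35 transcripts described as targets of nonsense-mediated decay, 4 rose and 7 fell (5 and 8 adjusted over the list alone; adjusted p = 0.275); UPP1 (0.96), DNAJB2 (0.38) and TMEM183A (0.16) rose, and TRA2B (-0.22) fell. Of 23 factors of that pathway 3 fell and 0 rose, also adjusted over the list alone: MAGOHB (-0.33), PNRC2 (-0.20) and MAGOH (-0.36), while EIF4A3 at -0.09 did not pass. Their list had a camera adjusted p of 0.0661 but passed in fry (adjusted p = 0.0196) and without the heavy library of line 1 (adjusted p = 0.0473). In camera with an estimated correlation that list had adjusted p = 0.539. Of 19 FMRP partners 1 rose and 3 fell (camera adjusted p = 0.0589). Of 35 deadenylation and decay genes 0 rose and 6 fell (4 adjusted over the list alone). Their adjusted p was 0.186 in camera, 0.0344 in fry and 0.571 in camera with an estimated correlation. Of 35 translation factors 4 rose and 3 fell (camera adjusted p = 0.602).

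Markers of cell identity moved in both directions. Of 33 adrenergic and catecholamine genes, 11 rose and 6 fell (13 and 11 adjusted over the list alone; camera adjusted p = 0.602): RET (log2 0.87), the noradrenaline transporter gene SLC6A2 (1.38) and the vesicular monoamine transporter gene SLC18A2 (2.41) rose, and ALK (-0.23) fell. Of 30 mesenchymal-type genes 8 rose and 6 fell (10 and 8 adjusted over the list alone; adjusted p = 0.741). S100A6 rose from 21.2 ± 1.26 to 52.6 ± 11.3 CPM, ANXA2 rose by 0.52 on the log2 scale, and LUM (-1.17) and TWIST1 (-0.41) fell. Of the 9 measured glial and Schwann cell genes 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.401): PMP22 (1.78), ERBB3 (1.17) and S100B (1.24) rose and SOX2 (-1.63) fell, the last 3 at mean levels under 2 CPM. The median of these 9 was -0.283 and -0.209 in line 3, against 0.732 and 0.601 in line 2 and 0.481 and 1.015 in line 1. Of 32 axon guidance genes 7 rose and 12 fell (9 and 14 adjusted over the list alone). The list had a camera adjusted p of 0.0523, and adjusted p = 0.339 with an estimated correlation. It passed on summed lines (0.0294), without line 1 heavy (0.0314) and in fry (0.00442). It also passed with the replicate number as a block (0.027), which pairs lines with wild type by number alone.

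The remaining lists did not pass in camera. Neurotransmitter receptors had 7 of 22 genes up and 4 down (adjusted p = 0.553), cadherins 5 of 22 up and 3 down (0.638), extracellular matrix 10 of 31 up and 3 down (0.908), the amino acid response 8 of 39 up and 2 down (0.553), and arginine, lysine and polyamine handling 6 of 31 up and 5 down (0.871). Fatty acid synthesis had 2 of 19 up and 7 down (0.198), heat shock genes 2 of 19 up and 2 down (0.908), hypoxia and glycolysis 6 of 31 up and 1 down (0.602), p53 targets 6 of 25 up and 0 down (0.19), and immediate early genes 2 of 24 up and 3 down (0.602). Cytosolic ribosomal proteins had 5 of 50 up and 0 down (0.31; 0 and 0 adjusted over the list alone), nuclear oxidative phosphorylation 1 of 36 up and 1 down (0.631; 0 and 0 adjusted over the list alone), histones 3 of 17 up and 2 down (0.602) and Wnt targets 3 of 18 up and 3 down (0.374). Adjusted over the list alone, receptors had 9 up and 5 down, cadherins 6 and 3, matrix genes 10 and 5 and arginine and lysine handling 8 and 5; the other counts of this paragraph did not change, nor did those of FMRP partners and translation factors. The median of p53 targets was 0.221 and 0.216 in the heavy and light libraries of line 3, and between -0.035 and -0.004 in lines 1 and 2. Median, mean and test differed in sign for targets of nonsense-mediated decay, deadenylation genes, matrix genes and heat shock genes.

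Within single media fewer genes passed. In heavy medium 18 of 16083 genes did, all higher in edgeR (646 higher and 170 lower in DESeq2, and 588 and 187 in edgeR with no filter on low counts), among them GPRASP2 (log2 3.74, edgeR adjusted p = 0.00895), GPRASP1 (4.01, adjusted p = 0.0429) and OAS3 (1.25, adjusted p = 0.0251). In light medium 231 of 16010 genes passed, 145 higher and 86 lower, with GPRASP2 at 3.92 (adjusted p = 9.16e-05), GPRASP1 at 4.07 (adjusted p = 0.00163), PTPRD at -1.56 (adjusted p = 0.0042) and FMR1 at -1.81 (adjusted p = 0.000404). At an unadjusted p under 0.05 the counts were 2885 and 4040. Counts in single media depended on single libraries. Without line 3 they were 2243 in heavy (1483 higher and 760 lower) and 6240 in light medium and without line 2 they were 307 and 71; without line 1 they were 19 and 24; without any 1 wild-type library they were 0 in heavy and 4, 4 and 5 in light medium. With the replicate number as a block, which pairs lines with wild type by number alone, 94 genes passed in heavy and 153 in light medium.

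**Figure D4:**
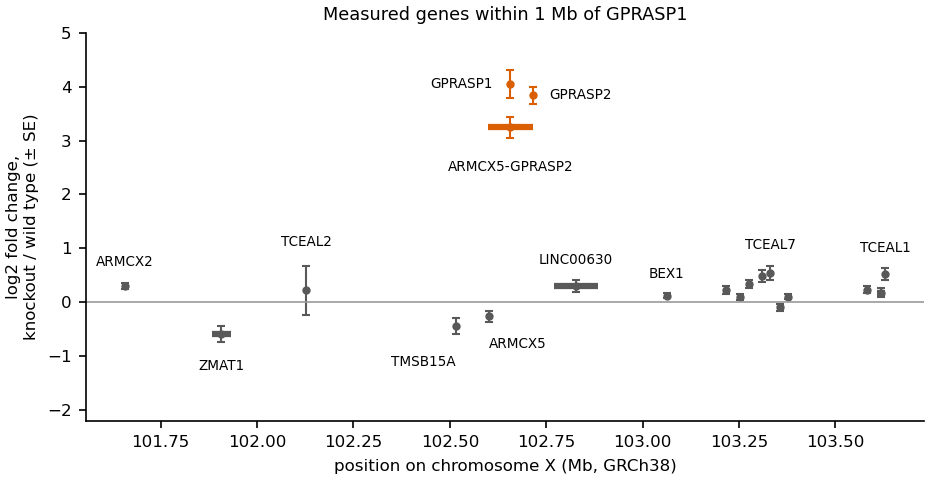
Log2 fold change of knockout against wild type over both media (points, with SE) for the genes tested within 1 Mb of GPRASP1 on chromosome X, by position on GRCh38. GPRASP1, GPRASP2 and ARMCX5-GPRASP2 lie between 3.25 and 4.05, and the 17 other genes between -0.59 and 0.55.

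The second factor was the medium, in which a label meant to leave cells unchanged is compared with its light counterpart. No single gene passed over both genotypes: 0 of 16704 in edgeR, DESeq2 and limma-voom, with 531 genes at an unadjusted p under 0.05 in edgeR. The smallest p values were those of AL355480.1 (log2 1.35 heavy over light, SE 0.264), AC006042.3 (0.63, SE 0.132) and RSRC2 (0.25, SE 0.053), each with an adjusted p of 0.999. With number within genotype as a block, 1 gene passed, AC006042.3 (adjusted p = 0.0383). In wild type 1 of 15845 genes passed, ID2, a BMP-responsive inhibitor of differentiation, named here after its value was seen (log2 0.47, SE 0.062, adjusted p = 0.0235); 808 genes had an unadjusted p under 0.05, and with the number as a block 13 genes passed. ID2 lost the call in 4 of the 6 fits that left out 1 wild-type library, those without heavy 2 and light 1, 2 or 3. In knockout 0 of 16206 genes passed in edgeR, DESeq2 and limma-voom, 138 of them at an unadjusted p under 0.05, and 0 with the line as a block.

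Some gene lists passed between media in camera with the preset correlation, by small medians and with 0 members past the threshold over all genes. DNA replication genes had a median log2 of 0.06 in heavy over light medium (camera adjusted p = 1.21e-07; adjusted p = 0.456 with an estimated correlation), with RRM2 at 0.14, RFC4 at 0.17, PCNA at 0.14 and CHAF1A at 0.12; in line 2 the median was lower in heavy than in light medium (-0.159 and -0.107 from the wild-type mean). Targets of nonsense-mediated decay had 0.065 (adjusted p = 2.04e-06; adjusted p = 0.481 with an estimated correlation), with RSRC2, HNRNPDL (0.13), SRSF6 (0.14) and TRA2B (0.11), but line 3 was lower in heavy medium (-0.140 and -0.086). The retinoic acid and BMP list had 0.16 (adjusted p = 5.25e-05; adjusted p = 0.456 with an estimated correlation), with ID4 (0.72), ID3 (0.18), ID2 (0.39) and HOXD4 (0.31), and immediate early genes 0.12 (adjusted p = 0.00504; adjusted p = 0.921 with an estimated correlation), with EGR2 (0.84), EGR3 (0.98), KLF6 (0.24) and BHLHE40 (0.68). The retinoic acid list was lower in heavy than in light medium in line 2 (-0.559 and -0.466 from the wild-type mean). Immediate early genes were not higher in heavy medium throughout: relative to the wild-type mean their medians were 0.292, 0.511 and -0.154 in heavy medium for lines 1, 2 and 3 and 0.023, 0.079 and -0.189 in light medium. In wild type they were -0.158, -0.061 and 0.134 in heavy and -0.035, 0.038 and 0.068 in light medium. The heavy library of line 1 lay between its light library and wild type over many genes, as described below. Values of line 1 are therefore no test of the medium.

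Cholesterol genes had a median of -0.085 in heavy over light medium, with 0 of 25 members past the threshold. Camera gave an adjusted p = 1.14e-06, and adjusted p = 0.481 with an estimated correlation. SREBF2 was at -0.13, MSMO1 at -0.17 and NSDHL at -0.11. Line 1 had -0.219 in heavy and -0.242 in light medium. The limit given above for its heavy library holds here, so line 1 does not speak against this list. Fatty acid synthesis had -0.045 (adjusted p = 0.0218; adjusted p = 0.456 with an estimated correlation), with FASN (-0.14), FADS2 (-0.09), ACLY (-0.06) and SREBF1 (-0.08); its medians in heavy and light medium were -0.030 and -0.084 in line 2 and -0.075 and -0.090 in line 3, the other way. Histones had -0.095 (camera adjusted p = 0.0311, and adjusted p = 0.456 with an estimated correlation). Among them were HIST1H1D (-0.79), HIST1H2AC (-0.20), HIST1H1E (-0.67) and HIST1H2BD (-0.14). With the filter at 1 CPM the histone list did not pass (camera adjusted p = 0.162). FMRP ligands had -0.02 (adjusted p = 0.0372; adjusted p = 0.921 with an estimated correlation), with KIF1A (-0.10), NCAN (-0.12), MAP1A (-0.10) and KMT2D (-0.08), but line 2 was not lower in heavy medium (0.147 and 0.132). Mitochondrial transcripts had -0.05 (adjusted p = 0.0372; adjusted p = 0.921 with an estimated correlation), with MT-ND1 (-0.13), MT-ND3 (-0.10), MT-CYB (-0.06) and MT-ND4 (-0.05), but line 1 was higher in heavy medium (0.339 and 0.304). A mix with wild type, whose heavy libraries lay at most at 0.066, would lower line 1 heavy and does not account for its value. No member of any list passed on its own over all genes, and RSRC2 alone passed when adjusted over the list alone. The other 27 lists had adjusted p between 0.0857 and 0.996. Lists past the threshold numbered 0 with an estimated correlation and 0 in fry, against 9 in camera with the preset correlation and 13 with the block. Median, mean and test differed in sign for receptors, adrenergic genes, cadherins, p53 targets, nuclear oxidative phosphorylation, heat shock genes, Notch and translation factors.

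The difference between knockout and wild type was not found to depend on the medium for any gene. The interaction passed for 0 of 16704 genes in edgeR, DESeq2 and limma-voom and 0 with the block, with 149 at an unadjusted p under 0.05 in edgeR. The smallest p values were those of the apolipoprotein gene APOC1 (log2 -1.62, SE 0.396), ANKRD29 (2.38, SE 0.601) and BTN2A3P (1.11, SE 0.282), each with an adjusted p of 1. A p above the threshold leaves differences open, also large ones such as that of ANKRD29, and the power of this test was not simulated.

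The last comparison asked how far the 3 knockout lines differ. The cancer-testis antigen gene MAGEA10 had line means of 43.4, 35.8 and 0.359 CPM in lines 1, 2 and 3 (edgeR adjusted p = 0.00067), and was at 0.145 CPM in wild type. Its range was 6.49; ranges are differences between line means of log2(CPM + 0.1), so for low genes they are smaller than the ratio of the mean CPM. The piRNA pathway gene GTSF1 had 25.4, 0.439 and 2.52 CPM (range 5.63), and the transporter gene SLC43A3 4.97, 0.0562 and 1.19 CPM (range 5.06). The ephrin receptor gene EPHB4 had 18, 2.06 and 41.4 CPM, against 44.7 ± 2.26 in wild type (range 4.27, adjusted p = 0.0218). Means of line 1 pool unlike libraries: heavy and light had 28.9 and 57.9 CPM for MAGEA10, 18.3 and 32.5 for GTSF1, 3.51 and 6.43 for SLC43A3 and 25.1 and 11 for EPHB4. EGFLAM (range 4.16), the neuropeptide Y receptor gene NPY2R (3.98), MIR100HG (3.97) and SMIM10 (3.79) were each highest in line 2 and lowest in line 3. For NPY2R the means were 4.11, 9.38 and 0.506 CPM, against 0.561 in wild type.

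Among the lines 2062 of 16206 genes differed, and 4354 had an unadjusted p under 0.05. Measured against wild type, 700 and 692 genes of line 2 in heavy and light medium and 638 of line 1 in light medium lay over 2-fold away, but 197 of line 1 in heavy medium and 85 and 93 of line 3. No wild-type library had such a gene. The count depended on single libraries: it was 3628 without line 1 heavy, 3567 without line 1 light, 228 and 693 without line 2 heavy and light, and 1327 and 717 without line 3 heavy and light. The comparison over both media moved with the lines too: without line 3, 7415 genes differed between knockout and wild type, without line 1 2327 and without line 2 1710. Leaving out 1 library moved it furthest downward without line 2 light (2632), line 1 light (2709) or line 2 heavy (2732).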

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

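All tests of explanations in this part were chosen only after the result was seen. The levels of named genes, the medians of the lists that passed and 3 measures of the libraries were searched within each genotype, 216 groups of 6 libraries, for a highest or lowest library too far from the others under Dixon's criterion. There were 7 such cases, where chance alone gives about 1 in 20 groups, or 10.8.

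FMR1 in the library labelled knockout line 1, heavy, stood at 22.5 CPM, above the 7.12 to 12.8 CPM of the other knockout libraries. The other cases were in wild type. In heavy library 1, FMR1 was at 42 CPM (36.2 to 37.3 in the others), CALR at 638 CPM (674 to 695), and the median of the FMRP family lay at 0.095 (log2) from the wild-type mean. In light library 1, CCDC3 was at 2.71 CPM (2.02 to 2.24), CRABP2 at 16.3 CPM (14.1 to 14.8), and the median of the neuronal differentiation list at 0.057.

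The library of line 1 in heavy medium lay between the light library of the same line and wild type over many genes, not FMR1 alone: MSN, for example, was at 24 CPM in wild type, 0.113 in line 1 light and 10.9 in line 1 heavy. Expressed as a share of wild type mixed with line 1 light, the median was 0.473 over 85 genes higher in wild type and 0.504 over 103 genes lower in wild type, which is what wild-type RNA or cells in this library would give; simulated shares of 0, 0.25 and 0.5 came back as 0.000165, 0.257 and 0.499. A response to heavy medium common to the lines is argued against by line 2, where the measure was -0.001 over 74 genes and 0.026 over 127 (in line 3 it was 0.032 and 0.001, over 4 and 8 genes, too few to count), and an admixture of line 3 by its share of 0 (bootstrap range 0 to 0.026) in a sum of 3 components, in which NECTIN2, at 14.4 CPM in line 3 heavy, stayed at 1.17 CPM in line 1 heavy. Whether such a mix may have arisen as RNA, cells or reads, or as unedited cells within line 1, stays open, and so does a state of that 1 culture. Not every list median lay between line 1 light and wild type. For mitochondrial transcripts it was 0.339 in line 1 heavy, 0.304 in line 1 light and at most 0.066 in wild type. For immediate early genes it was 0.292, 0.023 and at most 0.134. No further library of this line in heavy medium was analysed here.

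Among the knockout lines 2062 genes differed in the test of the difference itself. The ranges between line means of log2(CPM + 0.1) were 6.49 for MAGEA10, 5.63 for GTSF1, 5.06 for SLC43A3, 4.27 for EPHB4, 4.16 for EGFLAM, 3.98 for NPY2R, 3.97 for MIR100HG and 3.79 for SMIM10.

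Lines 1 and 2 were far from wild type in the same genes and line 3 was close to it. Loss of FMR1 with an equal effect in the 3 lines is argued against as the source of these large changes. In line 3, 702 genes over 2-fold from wild type in line 2 moved by a median of 0.188 of that change (bootstrap range 0.17 to 0.222). In line 1 light the median was 0.893. FMR1 mRNA was no higher in line 3, and 82.2% of the 702 genes moved to the same side there. These genes were picked by their change in line 2, so a smaller effect equal in the 3 lines was not tested. Only RNA was used here, so a difference between the lines in remaining FMRP stays open. Gain or loss of whole chromosomes is argued against as well, since the chromosome median farthest from wild type in line 1 light or line 2 was -0.048 (log2). Changes of line 1 light and line 2 correlated across 12496 genes with r = 0.903 when wild type was split between them. For either with line 3 it was 0.553 and 0.555. Over shared controls r was 0.917 with a covariance of 0.29. Unchanged lines simulated against those controls gave 0.245 and 0.00157. These simulated values show only what shared controls contribute and are no test of the likeness of lines 1 and 2. A common origin of lines 1 and 2 from a variant cell of the parent culture could give this likeness. A shared off-target edit or handling cannot be told apart from it, because the data hold RNA of these 3 lines alone.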

How the results depend on the processing

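Camera without the heavy library of line 1, camera with a block, summed lines with an estimated correlation, and summed lines with line 1 from its light library were chosen only after the result was seen; the other settings were fixed before the data were examined. No named fold change and no list past the threshold changed direction in the settings run for it; ranges among the lines have no sign. Lists that did not pass did change direction: for knockout against wild type mesenchymal (1 CPM filter), matrix (summed lines), amino acid response (without line 1 heavy) and heat shock genes (fry), and for the media 8 lists. Where a count moved the cause was not tested unless stated. For knockout against wild type over both media (4135 genes), 272 passed on counts summed per line and 274 with line 1 from its light library, in fits with fewer samples; 206 passed in glmTreat, which asks for a fold over 1.5, and 87.4% of those were higher, against 60.5%. Without line 1, 2 or 3 the counts were 2327, 1710 and 7415, and with 1 library left out they lay between 2632 and 5907 (3788 without line 1 heavy). RLE factors (4155), DESeq2 (4667), limma-voom (4025), no filter (3492), a filter at 1 CPM (3981), the replicate block (4484) and the line as a correlated block (3205) kept the count within 1.5 times.

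In heavy medium (18 genes) DESeq2 gave 816, limma-voom 1 (ZNF663P, named after its value was seen), no filter 775, the 1 CPM filter 9, the replicate block 94 and a spread shared by all 12 libraries 99; with 1 library left out the range was 0 to 2243. In light medium (231) DESeq2 gave 1718, limma-voom 135, no filter 1351, the replicate block 153 and the shared spread 616; with 1 library left out the range was 4 to 6240. The 4 genes past the threshold without wild-type light 1 or light 2 were GPRASP2, ARMCX5-GPRASP2, FMR1 and DNAJC15, the last named after its value was seen, and GPRASP1 joined them without light 3.

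For the media over both genotypes (0) the replicate block gave 1; wild-type numbers do not pair libraries, so that block rests on the knockout lines. In wild type (1) DESeq2 gave 3 (ID2, PLXNA2 and SAMD11), no filter 39, the replicate block 13 and the shared spread 0; with 1 library left out the range was 0 to 8. The media in knockout and the interaction stayed at 0 in all settings run. Among the lines (2062) no filter gave 3411 and leaving out 1 library 228 to 3628.

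Lists past the threshold for knockout against wild type (12) fell to 0 with an estimated correlation, also on summed lines (0); they numbered 11 in fry and 13 each on summed lines, with the block and without line 1 heavy. For the media (9) they were 0 with an estimated correlation, 0 in fry, 13 with the block, 12 without line 1 heavy and 8 with the 1 CPM filter. DESeq2 and RLE factors changed no call of the 92 named values for knockout against wild type. Nor did the replicate block, which pairs lines with wild type by number alone and so is no check of these calls. On summed lines 36 kept their call and 56 did not pass. With line 1 from its light library 29 kept their call and 63 did not pass, and in glmTreat 27 and 65. Depth limits the low genes: ISG15 in wild type, at 0.238 CPM, rests on few reads per library.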

Other observations

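The tests in this part were chosen only after the result was seen, except the random regroupings for heavy against light medium, for its gene lists and for the interaction. Some genes were nearly silent in 1 state and well expressed in the other. Counting genes at 5 CPM or more in wild type that were at least 10-fold below the wild-type mean in every library of a line, limits set after the values were seen, 40 genes were nearly lost in line 1 (light library) and 35 in line 2, and 31 were the same genes. They include transcription factors and regulators of neural development, such as MEIS1 (81.2 ± 5.16 CPM in wild type, SD, n = 6; 7.28 in line 1 light, 7.61 and 7.97 in line 2), BCL11A, LMO4 and TEAD2 (68.5 CPM; 0.255, 0.927 and 1.5). They also include the planar polarity gene PRICKLE1 (125 CPM; 4.11, 4.02 and 4.43), the growth factor genes BMP7 and HGF, the glutamate receptor genes GRM8 and GRIK3, the cadherin gene CDH11 and the complement gene C7. In line 3 TEAD2 was at 72.5 and 79.2 CPM and PRICKLE1 at 107 and 101 CPM, but HGF, at 24.4 CPM in wild type, was at 10.2 and 5.16 CPM.

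Genes at least 10-fold above all wild-type libraries, and at 5 CPM or more, numbered 29 in line 1 light and 29 in line 2, of which 22 were the same. The neuropeptide gene NPY went from 3.27 ± 0.496 CPM (SD, n = 6) in wild type to 128 in line 1 light and 148 and 151 in line 2, with 24.5 and 20.4 in line 3. The receptor gene EGFR went from 5.04 to 124, 71.4 and 65.8 CPM, and SHISA5, SCG5, FAM20C, TNFRSF1A, PRPH and MET were in the same set. Independent lists of these sizes would share 0.128 genes lost and 0.0727 gained. With wild type split between the lines the shared numbers were 30 and 30 lost and 22 and 25 gained. In simulated unchanged lines they were 0, but lines without 10-fold changes can hardly give another number, so this adds no support. No wild-type library had such a gene against the other 5. Line 3 had 1 gene lost and 1 gained, and both were shared by lines 1 light and 2. The gene gained was GPRASP2. The floor of 5 CPM left out some genes that rose in line 3 from very low levels. TNFRSF1A went from 0.0199 CPM in wild type to 2.09 and 2.03 there, and FAM20C from 0.121 to 3.48 and 3.58. MAGEA10 reached only 0.398 and 0.321 CPM in line 3, from 0.145. GPRASP1 missed the limit in line 3 with 13.5 and 13.9 CPM against a wild-type mean of 1.2. The gene lost was MSN, which encodes moesin, a linker of membrane and actin: it fell from 24 ± 1.31 CPM to 0.113 in line 1 light, 0.225 and 0.115 in line 2 and 0.63 and 0.748 in line 3 (edgeR adjusted p = 0.0179 over both media, 0.128 on summed lines). In line 1 heavy MSN was at 10.9 CPM.

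GPRASP1, GPRASP2 and the readthrough ARMCX5-GPRASP2 rose together in all 3 lines, on the chromosome that carries FMR1. Extra copies of a region that reaches the neighbours are argued against: of the 17 other genes measured within 1 Mb the highest, TCEAL7, was at 0.55 (log2, SE 0.128), and ARMCX5, which overlaps the readthrough, was at -0.26. A first look at the median of these genes, 0.22 (bootstrap range 0.1 to 0.3), had left copies undecided, and a gain narrow enough to hold the 3 genes alone stays open. For GPRASP1 reads shared with the others are argued against by 0 exon bases in common; for ARMCX5-GPRASP2, with 281 of its 2711 exon bases shared with GPRASP2, its rise and reads of GPRASP2 cannot be told apart.

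Other splits of the libraries into groups of the same sizes were fitted in the same way. For knockout against wild type over both media, the real split gave 4135 genes and was the highest, 1 of 100 splits, which excludes chance only if the 12 libraries are taken as independent. The 6 knockout libraries are 3 lines, and with a line as the unit 3 against 3 make 10 splits, too few for a share under 0.05. The next gave 3926 and exchanged line 3 light for wild-type heavy 3. For its gene lists, with 12 past the threshold, 31 of 100 splits gave as many and the highest other gave 17, so chance is not excluded. For the lists of heavy against light medium over both genotypes, with 9 past the threshold, 47 of 100 gave as many and the highest other gave 20, so chance is not excluded. Where the real count was 0 genes any split gives as many, so the tally says nothing about chance: it was 100 of 100 for heavy against light medium over both genotypes, the highest other giving 762, and 100 of 100 for the interaction, with 2303 as the highest other. The splits with 762 and 2303 genes both kept line 1 light and both libraries of line 2 in 1 group, a structure of the lines.

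Sets of 3 against 3 libraries make 10 splits, too few for a share under 0.05. The real values and the highest of the others were 18 and 0 for knockout against wild type in heavy medium, 231 and 0 in light medium, and 1 and 0 for the media in wild type, each with 1 of 10 splits as large. For the media in knockout they were 0 and 2975, where 10 of 10 as large follows from the real count of 0. The split with 2975 genes set line 1 heavy and both libraries of line 3 against line 1 light and both of line 2, a structure of the lines; the 4 splits that part all 3 lines, the real one among them, gave 0.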
